A study of Mus musculus with 12 samples.

How the data were processed

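Fetal membranes of wild-type and DKO mice at E12 and E18 were sequenced as 12 libraries, 3 for each of 4 groups. The labels' protocols describe RNA extracted from frozen, ground membranes and libraries made with a stranded mRNA kit. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.4.2a and featureCounts from Subread 1.5.0, with the mouse genome build GRCm38. Per the file headers, reads were assigned to genes of Ensembl release 86 with featureCounts 1.5.0 and strand option 2, without the option that counts reads aligned to several places. The deposited values are raw gene counts, whole numbers with no normalization, per the file headers. Near-identical copies, pseudogenes and overlapping genes can therefore lose or exchange reads, and such genes are given as uncertain.

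A series table held counts for all 12 libraries and 48795 genes. The files of 11 libraries matched 1 column of it exactly, and the file of E12 DKO 1 held no count column, so its counts come from the series table. The columns of the libraries labelled E18 WT carry the numbers 2 to 4 and their titles the numbers 1 to 3, and they were joined by identical counts. Symbols were found for 48349 gene IDs in the gene name table, and coordinates are those of the files. Total counts ranged from 19967593 to 33065424 per library. At that depth a gene at 0 in 1 library is bounded by a floor of 3 counts per library. Such floors and the counting intervals (95%) cover counting error only.

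Groups follow the labels. The tests, the samples in each fit, the gene lists, the rule for named genes and all alternatives except those said to be later were chosen before the data were examined. Genes were filtered with filterByExpr on the group factor, leaving 18153. Counts were normalised with TMM factors in edgeR 4.0.16 (R 4.3.3), and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 0.373). Fitted within each group, that coefficient was 0.177 in E12 DKO, 0.545 in E12 WT, 0.331 in E18 DKO and 0.338 in the libraries labelled E18 WT. The contrasts were DKO against WT at each stage, the difference of these, and E18 against E12 in each genotype. P-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, called under 0.05 with no fold threshold. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-normalised library sizes.

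In all 40 gene lists were fixed, 21 of processes and 19 of cell markers, and 38 had at least 5 tested members. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted by Benjamini-Hochberg over the lists. Counts "adjusted over the list alone" readjust the p-values within a list. Named genes were, in each genotype comparison, Bgn and Dcn, then the 10 largest rises and 10 largest falls among called genes with a mean of 5 CPM or more, no overlap between the groups and a conventional symbol. Up to 4 members of each list with the lowest adjusted p and all small leucine-rich proteoglycans were added. The stage comparisons took 8 in each direction and the difference 6. Some genes that met this rule are not reported here. Overlap of calls and the share of calls within 10 Mb of Dcn or Bgn were tested with two-sided Fisher exact tests.

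The procedure was tested on simulated counts drawn from the real means, library sizes and spread, with 100 genes changed 2-fold and 100 changed 4-fold among 18153. For DKO against WT at E12, 9% of the 2-fold and 63% of the 4-fold changes were called, with 0.0223% of unchanged genes called. At E18 the shares were 9%, 70% and 0.0167%. A list raised in the simulation was called at both stages and 0 other lists were. Each simulated gene was drawn independently, with the same spread in every group. The simulation therefore does not test list calls among correlated genes. Nor do its shares allow for the unequal spread of the real groups, such as 0.177 in E12 DKO and 0.545 in E12 WT.

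Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma voom, no filter, a filter of 1 CPM in at least 3 libraries, a 2-fold threshold, the replicate number as a block, the Y-linked mean as a covariate, only the groups compared, windows of 5 and 20 Mb, and each library left out in turn. A fit without E12 WT 1 and library 3 labelled E18 WT was added after the data had been seen. Other splits of the 6 libraries of each comparison were refitted, 10 in all, and 60 were drawn for the difference. For the closing tests, the positions on the stage axis, the limits for genes switched on (2 CPM or more in every library) or off (under 0.2 CPM) and the late-fraction genes were set after the values had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main comparisons, and no data on fibril structure, protein or birth timing were used here.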

Results

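Gene expression was measured by RNA sequencing in mouse fetal membranes, the sacs that enclose the fetus, at embryonic days 12 (E12) and 18 (E18). The mice were wild-type (WT) or carried a double knockout (DKO) of biglycan (Bgn) and decorin (Dcn), a pair of small leucine-rich proteoglycans that bind collagen fibrils. There were 12 libraries in 4 groups of 3. The labels give the strain as C3H for both wild-type groups and as C3H and C57BL/6 for both DKO groups, so strain and genotype could not be separated. Total counts per library ranged from 19967593 to 33065424, over 48795 annotated genes, of which 18153 had enough counts to be tested. The question, from the series' title and design, was how loss of both proteoglycans changes the membrane transcriptome at each stage, in a model of preterm birth.

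Both targeted genes were far lower in every DKO library than in every wild-type library. Bgn (GRCm38 chromosome X, 73483602 to 73495933) was at 16.4, 16.2 and 14.3 CPM (counts scaled to a common library size of 1e6) in the E12 DKO libraries and at 686, 270 and 357 CPM in the E12 WT libraries. In the E18 DKO libraries it was at 25.1, 23.9 and 24.6 CPM, against 239, 223 and 381 CPM in the libraries labelled E18 WT. Dcn (chromosome 10, 97479500 to 97518162) was at 5.92, 8.44 and 6.95 CPM in E12 DKO and at 762, 235 and 325 CPM in E12 WT. It was at 4.67, 4.78 and 6.21 CPM in E18 DKO and at 198, 353 and 978 CPM in the libraries labelled E18 WT. The log2 fold changes of Bgn were -4.81 ± 0.36 at E12 (SE, n = 3 per group, adjusted p = 0.000595) and -3.52 ± 0.34 at E18 (adjusted p = 9.7e-05). Those of Dcn were -5.95 ± 0.67 at E12 (adjusted p = 0.0134) and -6.61 ± 0.69 at E18 (adjusted p = 0.000126). Single libraries moved Dcn, to -5.30 at E12 without E12 WT 1 and to -5.72 at E18 without library 3 labelled E18 WT. The E12 call of Dcn was lost without E12 DKO 1, 2 or 3 (adjusted p = 0.0895, 0.0938 and 0.109) and with the Y-linked covariate (0.0535), and both genes missed the threshold at E12 when only those 6 libraries were fitted (0.0714), with the direction unchanged. Genotype labels and targeted genes therefore matched in all 12 libraries, and the counts do not say whether the residual reads come from an undeleted part of either gene.

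**Figure D1:**
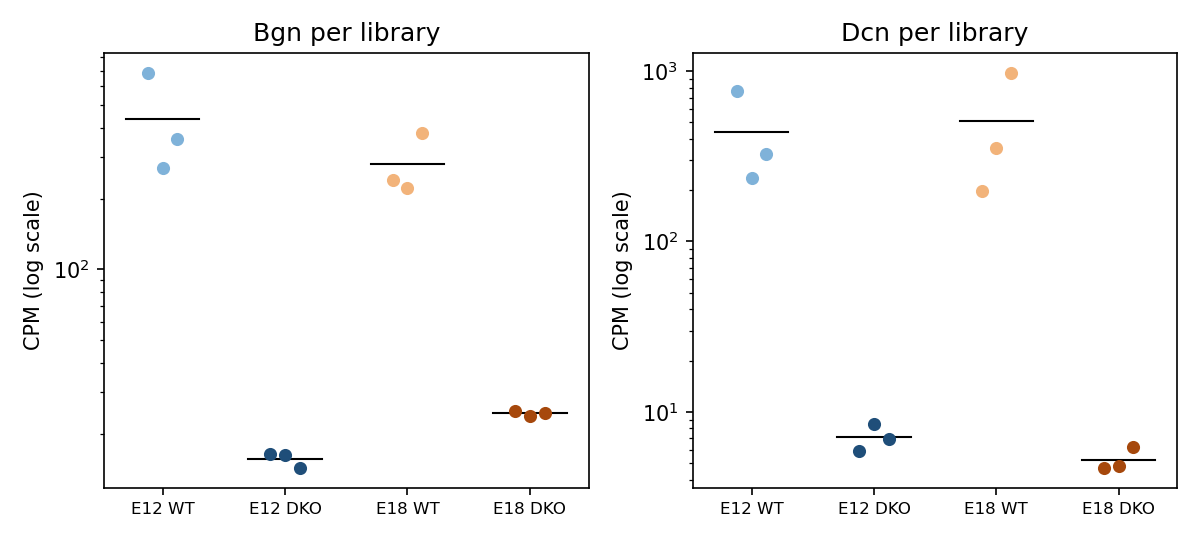
Normalised CPM of Bgn and Dcn in each library on a log scale; each point is 1 library and each line is the mean of 3. Every DKO library lies below every wild-type library, at 25.1 CPM or less for Bgn and 8.44 CPM or less for Dcn.

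The stage labels of the wild-type libraries did not match stage markers in the same way. Hbb-y and Hbb-bh1, the embryonic beta-globins of primitive red cells, made up 82.3 to 85.1% of beta-globin counts in the E12 DKO libraries and 1.33 to 2.67% in the E18 DKO libraries. In the libraries labelled E18 WT they made up 81.4% (95% exact binomial interval 81.2 to 81.6), 87.8% (87.6 to 87.9) and 74.8% (74.6 to 74.9). In the E12 WT libraries they made up 14.8% (14.6 to 15.1), 95.1% (95 to 95.1) and 97.1% (97 to 97.1), so that E12 WT 1 stood apart. These intervals cover counting error only. On an axis from the E12 DKO mean (position 0) to the E18 DKO mean (position 1), drawn after the values had been seen over the 8349 genes that differed between the DKO stages, the libraries labelled E18 WT lay at 0.074, 0.031 and 0.185. The E12 WT libraries lay at 0.516, 0.096 and 0.166. Library 3 of those labelled E18 WT also held 71.4 CPM of Prl8a2 and 165 CPM of Prl3b1, transcripts of decidua and trophoblast, against at most 2.12 and 16.4 CPM in the other 11. E12 WT 3 drew 21.2% of its counts from mitochondrial genes, against 3.58 to 7.78% in the others. These libraries were kept in their labelled groups, and each comparison below that uses the libraries labelled E18 WT inherits this uncertainty about their stage.

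**Figure D2:**
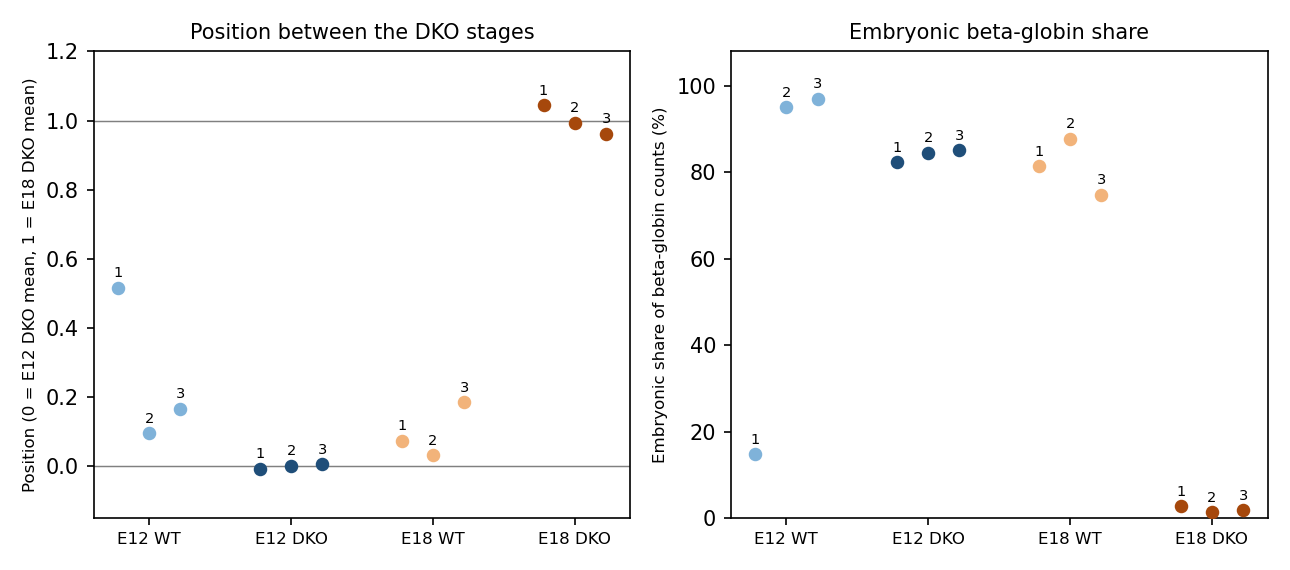
Left, position of each library between the E12 DKO mean (0) and the E18 DKO mean (1) over 8349 genes; right, percent of beta-globin counts from Hbb-y and Hbb-bh1. Numbers beside the points are replicates; the 3 libraries labelled E18 WT lie at 0.185 or less on the left and at 74.8% or more on the right, near the E12 libraries.

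The E12 comparison asks what changes in the membranes well before term. Beside the targeted genes, Hbegf, a ligand of the epidermal growth factor receptor, fell in the DKO (log2 fold change -3.76 ± 0.56, SE, n = 3 per group, adjusted p = 0.0305). Hba-a1, an alpha-globin, was at -2.81 ± 0.46 and Car2, carbonic anhydrase 2, at -1.58 ± 0.29. Tspo, a protein of the outer mitochondrial membrane, fell by 1.81 on the log2 scale, Prdx5, a peroxide-reducing enzyme, by 1.14, and Dhrs3, which reduces retinaldehyde, by 1.11. Rises were smaller, among them Slfn9 (1.76 ± 0.30), Scoc (1.60 ± 0.26), Zfp125 (1.58 ± 0.26), the nuclear transport receptor Xpo4 (1.55 ± 0.27), F13a1, the A subunit of coagulation factor XIII and a macrophage marker (1.36 ± 0.21), and Arl5a (1.30 ± 0.21). Mtx3, Syt14 and Epm2aip1 rose by 0.94 to 1.01, and Rtl8b, Nme7 and Epb41l4aos fell, with log2 fold changes of -2.05, -1.64 and -1.58. Hba-a1 has a near-identical neighbour, Hba-a2, which was at 8.88 and 6.59 CPM in E12 WT 2 and 3 but at 791 CPM in E12 WT 1, so the value of either globin gene alone is uncertain.

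In all, 64 genes changed at E12, 17 higher and 47 lower in the DKO, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and 4416 had an unadjusted p under 0.05. The CPM of the 2 genotypes did not overlap in 5462 genes, or 30.1%, where chance gives 10%. The count rests on single libraries: it was 3248 (1325 higher, 1923 lower) without E12 WT 1, 244 without E12 WT 2, 9 without E12 WT 3, and 2, 1 and 2 without E12 DKO 1, 2 and 3. Each called gene of the paragraph above lost its call without any 1 of the E12 DKO libraries and without E12 WT 3, in the same direction. All 64 remained called without E12 WT 1, whereas 0 were called when only these 6 libraries were fitted, 1 with the Y-linked mean as a covariate, and 2073 by the DESeq2 Wald test. Through the shared fit, 14 to 52 of the 64 remained called when 1 of the 6 E18 libraries was left out. Of the 64, only Bgn, Dcn and Zdhhc9 were among the 34 genes called between E12 DKO and the libraries labelled E18 WT. That comparison was chosen after the data were seen. The genes of the paragraph above were thus not called against the second wild-type group, whose stage is in doubt. Scaling by library size alone gave 55 genes, 41 higher and 14 lower, and shifted the median of all genes by 0.30, so that the balance between rises and falls at E12 depends on the scaling.

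Among the small leucine-rich proteoglycans, the family of the targeted genes, only Bgn and Dcn passed of 14 tested at E12, over all genes and adjusted over the list alone. Lum was at -0.66 ± 0.24 (adjusted p = 0.14) and Fmod at 0.56 ± 0.31 (adjusted p = 0.288). Prelp was at -0.42 ± 0.63 (adjusted p = 0.717) but rose by 1.27 ± 0.23 without E12 WT 1 (adjusted p = 0.00872), since it was at 101 CPM in that library and at 15.3 and 10.9 CPM in E12 WT 2 and 3. None of 22 fibrillar and associated collagens passed over all genes and 1 rose adjusted over the list alone, with Col12a1 at 1.68 ± 0.38 (adjusted p = 0.0703). Without E12 WT 1, 3 collagens were higher and 1 lower, and 1 of the proteoglycans was higher and 3 lower, over all genes and adjusted over the list alone.

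Of 38 lists fixed before the data were examined, 10 were called at E12 by camera with a preset correlation, 1 higher and 9 lower, and 0 with an estimated correlation. The cell cycle list was higher, although 0 of its 35 members passed singly or adjusted over the list alone (median 0.42, adjusted p = 0.717 with an estimated correlation). The lower lists with members that passed were definitive erythroid genes, with 2 of 13 lower (5 adjusted over the list alone, adjusted p = 0.711 with an estimated correlation), and retinoid metabolism, with 1 of 19 lower (1 adjusted over the list alone, 0.711). Lower lists with 0 members passed over all genes were primitive erythroid genes (5 of 8 lower adjusted over the list alone), amnion-type epithelium (11 of 25), endothelium (4 of 22), immediate early genes (13 of 18), mitochondrial transcripts (6 of 7), hypoxia and glycolysis (0 of 30), and elastic fibre and crosslinking genes (0 of 29). With an estimated correlation each of these 7 had an adjusted p of 0.711. Without E12 WT 1, 4 lists were called, all lower: mitochondrial transcripts, both erythroid lists and the oxidative stress response, each with adjusted p = 0.936 with an estimated correlation. The mitochondrial list moved with the high mitochondrial share of E12 WT 3 and was no longer called without that library.

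The E18 comparison asks the same question near term, against libraries that carried the embryonic globins and early positions given above. Genes of cell division were lower in the E18 DKO: Kif11, a spindle motor, was at -5.45 ± 0.50, the chromosomal passenger Birc5 at -5.40 ± 0.50, and Top2a, which untangles replicated DNA, at -5.02 ± 0.48 (SE, n = 3 per group). The collagen genes Col2a1 (-7.57 ± 0.72) and Col9a3 (-6.55 ± 0.88) were lower as well. The embryonic globins Hbb-y and Hba-x fell by 8.70 and 8.01 on the log2 scale. In the other direction, the acute-phase inhibitor Serpina3n was at 10.34 ± 1.29, the iron-carrier binding protein Lcn2 at 7.82 ± 1.16, and Igfbp3, which binds insulin-like growth factors, at 4.37 ± 0.33. Without library 3 labelled E18 WT, Lcn2 was at 10.20 and Serpina3n at 11.33.

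Several genes were close to absent in 1 of the 2 groups, so that only counting bounds apply. Against a floor of 3 counts per library, the histone gene Hist1h2al, at 0 counts in the libraries labelled E18 WT, was at least 153-fold higher in E18 DKO, and the cornified-envelope gene Cnfn at least 41.5-fold higher. Hist1h2al belongs to a family of near-identical histone genes, so its value is uncertain. Vsig1, with 3 counts in the libraries labelled E18 WT, was 2150-fold higher in E18 DKO (95% counting interval 735 to 10400), and the carboxylesterase Ces3a 1950-fold higher (666 to 9450). The milk casein Csn2 was 954-fold higher (171 to 37700), Dppa1 1780-fold (318 to 70200), Scgn 1390-fold (250 to 55100) and Cyp4a32 802-fold (274 to 3890). Single libraries moved the fitted log2 values of these rises, all still called. Csn2 went from 9.43 to 8.72 without E18 DKO 1. Without library 2 labelled E18 WT, Csn2 was at 11.14 and Scgn at 11.64 (9.92 with it). Dppa1 went from 10.24 to 12.04 without library 3 and Vsig1 from 10.88 to 11.76 without library 1. The casein Csn1s2b, with more counts, was at 10.25 ± 0.77. Among the falls, the GABA receptor subunit Gabrp was at -9.27 ± 2.09, Zfhx4 at -8.10 ± 1.14 (-9.99 without E18 DKO 3), the glutamate receptor subunit Gria1 at -7.93 ± 1.59 and Hsd3b6, a steroid-synthesis enzyme, at -7.81 ± 1.12. Glyat, a glycine acyltransferase, was 608-fold higher in the libraries labelled E18 WT (interval 109 to 24100), Hoxd13 647-fold (116 to 25600), Otof 713-fold (128 to 28200) and Aldh3b2 280-fold (77.4 to 2320). Single libraries carried much of some of these falls. Without library 3 labelled E18 WT, Gabrp was at -7.17, Gria1 at -6.20, Otof at -7.96 (-9.18 with it) and Aldh3b2 at -6.23 (-8.04), and without library 1 Hoxd13 was at -6.70 (-9.07), all still called. The call of Cnfn (adjusted p = 0.0282) ended without any 1 of the libraries labelled E18 WT (0.0618 to 0.0719) and without E18 DKO 3 (0.0698). Serpina4-ps1 was at 9.97 ± 1.63 and is a pseudogene, so its reads can be shared with related genes.

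The small leucine-rich proteoglycans split at E18. Of 14 tested, 6 were lower, with Ogn at -3.11 ± 0.26, Fmod at -3.53 ± 0.35, Lum at -2.70 ± 0.26 and Chadl at -1.74 ± 0.56 beside Bgn and Dcn. The 4 that rose were Podn (2.78 ± 0.68), Chad (2.27 ± 0.60), Tsku (0.89 ± 0.31) and Nyx (3.24, adjusted p = 0.0484), and the same numbers passed adjusted over the list alone. Nyx was at 1.54 without E18 DKO 3 (adjusted p = 0.292), and its call also ended without any 1 of the libraries labelled E18 WT (0.0889 to 0.129). Those of Tsku and Chadl ended in 4 of the 6 fits with 1 library left out, Tsku without E18 DKO 1 or 2 or library 1 or 2 labelled E18 WT (0.0951 to 0.132) and Chadl without E18 DKO 1 or 3 or the same 2 wild-type libraries (0.0506 to 0.118). Chadl was at -2.34 without E18 DKO 2. As a set they were not called (adjusted p = 0.203, and adjusted p = 0.775 with an estimated correlation). Of 22 fibrillar and associated collagens 13 fell and 2 rose, also adjusted over the list alone, and Col1a1, the main collagen of the membrane stroma, was at 1360, 892 and 1980 CPM in the E18 DKO libraries against 6060, 6910 and 11600 CPM in those labelled E18 WT. That list was called lower (adjusted p = 0.000538, but adjusted p = 0.483 with an estimated correlation). Other matrix lists were mixed and not called: 8 of 25 basement membrane genes rose and 5 fell, 5 of 29 elastic fibre and crosslinking genes rose and 8 fell, 9 of 34 matrix proteases and inhibitors rose and 7 fell, and 8 of 25 other proteoglycans and hyaluronan genes rose and 7 fell. Adjusted over the list alone, 9 basement membrane genes rose and the other 3 lists kept these counts. Examples were Lama5, a laminin chain (1.29 ± 0.32), Tgm2, a crosslinking transglutaminase (2.80 ± 0.30), Fbln1 (-3.22 ± 0.43), Mmp11 (-1.46 ± 0.22) and the hyaluronan synthase Has1 (6.68 ± 1.13).

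Among cellular processes at E18, 34 of 35 cell cycle genes fell, also adjusted over the list alone, with a list median of -4.13. Cholesterol synthesis fell in 19 of 24 genes (21 adjusted over the list alone), with Insig1, which holds back sterol synthesis, at -3.12 ± 0.31 and the lanosterol synthase Lss at -2.36 ± 0.21. Wnt genes fell in 16 of 31 and rose in 2 (17 and 2 adjusted over the list alone), with the Wnt feedback inhibitor Rnf43 at -5.31 ± 0.48 and Wnt5b at -3.94 ± 0.56 (-4.58 without E18 DKO 1). Interferon-stimulated genes rose in 26 of 34 and fell in 0 (31 adjusted over the list alone), with Irf7 at 3.30 ± 0.48 and Usp18 at 3.74 ± 0.56. Immediate early genes, which can also rise during tissue handling, rose in 14 of 18 (16 adjusted over the list alone), with Socs3 at 3.83 ± 0.39 and the heat-shock gene Hspa1a at 3.46 ± 0.33. The list of p53 targets and senescence had 13 of 26 higher and 2 lower (14 and 2 adjusted over the list alone). All 6 of these lists were called with a preset correlation, cell cycle, cholesterol synthesis and Wnt lower and the other 3 higher. With an estimated correlation the adjusted p was 0.522 for Wnt and 0.483 for the other 5.

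Among cell type markers at E18, all 8 primitive erythroid genes fell, also adjusted over the list alone, as did 7 of 13 definitive erythroid genes against 1, Car2, that rose (8 and 1 adjusted over the list alone). Endothelial genes rose in 11 of 22 and fell in 2, also adjusted over the list alone, with Robo4 at 2.32 ± 0.18 and the lymphatic marker Lyve1 at 1.60 ± 0.19. Genes of cornifying epidermis rose in 4 of 7 (5 adjusted over the list alone), with Sbsn at 4.26 ± 1.04 (5.88 without library 3 labelled E18 WT). The primitive erythroid list was called lower and the endothelial and cornifying lists higher with a preset correlation, each with adjusted p = 0.483 with an estimated correlation; the definitive erythroid list was not called (adjusted p = 0.11). Amnion-type epithelial genes went both ways, 11 of 25 higher and 7 lower (11 and 8 adjusted over the list alone), with Krt7 at 2.05 ± 0.26 and Grhl3 at -6.61 ± 1.16 (-5.68 without library 3 labelled E18 WT, -7.61 without E18 DKO 2). Their median was -0.11 and their mean -0.43, while the set test pointed up (adjusted p = 0.279). Macrophage genes rose in 9 of 22 and fell in 3, also adjusted over the list alone, without a list call (adjusted p = 0.0594). Of 26 trophoblast genes 5 fell (2 adjusted over the list alone), among them Phlda2 at -2.88 ± 0.64 (-3.84 without E18 DKO 3), beside the trophoblast and decidua transcripts in library 3 of those labelled E18 WT.

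In all, 7678 genes differed at E18, 3725 higher and 3953 lower in the DKO, and 5613 of them by 2-fold or more. The CPM of the 2 groups did not overlap in 10322 genes, or 56.9%, where chance gives 10%. By library size alone the split was 2382 higher and 6015 lower, with the median of all genes shifted by -0.36, so the balance of rises and falls also depends on the scaling here. Of 10 lists called, 5 higher and 5 lower, 0 were called with an estimated correlation, and fry, which asks only whether a list moves one way, called 18. Each of the 10 had a median of the same sign for E18 against E12 within the DKO, a comparison that shares the E18 DKO libraries. The cell cycle median was -4.13 here and -4.08 there, that of interferon-stimulated genes 2.15 and 2.38. Cholesterol synthesis was at -1.8 and -1.87, primitive erythroid genes at -6.41 and -5.69, and Wnt genes at -1.63 and -0.39. Stage and genotype are therefore not separated in these lists.

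**Figure D3:**
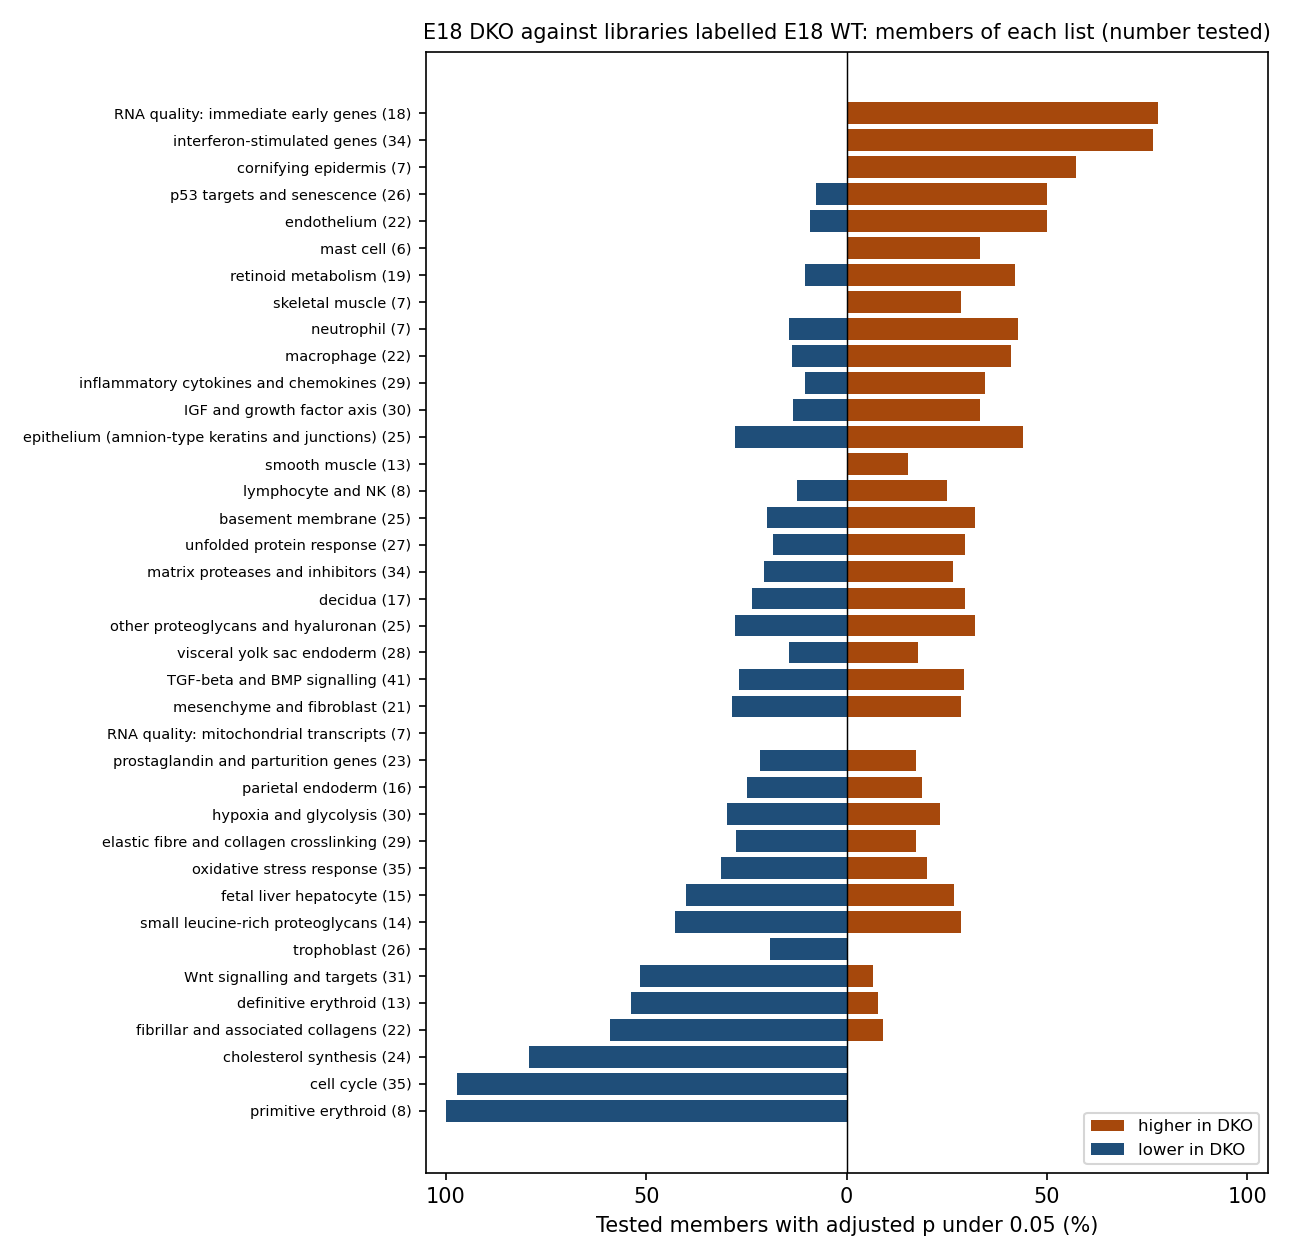
Percent of the tested members of each list that were higher (right) or lower (left) in E18 DKO than in the libraries labelled E18 WT, with the number tested in brackets. All 8 primitive erythroid and 34 of 35 cell cycle genes were lower, and 26 of 34 interferon-stimulated genes were higher.

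The difference between the genotype effects at the 2 stages was tested directly. Among the largest differences, Ces3a differed by 14.71 on the log2 scale, Vsig1 by 14.38, Serpina3n by 14.36 and Slc51b, a bile acid transporter subunit, by 14.07, each higher in the DKO at E18 and not passing at E12. In the negative direction were Zfhx4 (-9.53), Glyat (-9.46), Col2a1 (-9.25), the placental prolactin-family gene Prl7a2 (-8.67), Gabrp (-8.40) and Gria1 (-8.20). The pseudogenes Rpl15-ps2 and Serpina4-ps1 were at 19.5 and 16.2, and their reads can be shared with related genes. Rpl15-ps2 was on in some and off in other libraries of 1 group, at 6.38, 0.0853 and 11.8 CPM in E18 DKO. It is among the 17 genes described below that were on in every E12 WT library and off in every library labelled E18 WT. Several of the genes with these largest differences had 3 counts or fewer in a group, so the fitted sizes depend on the prior count and are no bounds. Without E12 WT 1 the differences were 9.99 for Ces3a, 10.22 for Vsig1, 12.09 for Serpina3n and 11.01 for Slc51b. Without library 3 labelled E18 WT they were -3.75 for Prl7a2, no longer called (adjusted p = 0.194), -6.30 for Gabrp and -6.47 for Gria1. The difference of Prl7a2 also lost its call without any 1 of the E12 libraries (0.0541 to 0.0845) and without E18 DKO 1 or 3 (0.075 and 0.0721). In all, 7600 genes differed, 3921 in the positive and 3679 in the negative direction (2187 and 6438 by library size alone). Of the 289 genes named in either genotype comparison, 230 differed between the stages, against 41.9% of all tested genes. The 289 were chosen from the same 2 contrasts, which favours a high share.

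Few genes changed the same way at both stages. Bgn, Dcn, Hba-a1 and Zdhhc9, a palmitoyltransferase chosen here after its values were seen, were lower in the DKO at both, and 0 genes were higher at both. That compares with 10.2 and 3.49 for independent lists of these sizes. Another 55 genes were called at both stages in opposite directions. Across all tested genes, which are not independent replicates, the log2 fold changes at the 2 stages had a Pearson r of -0.445 and a Spearman rho of -0.47. Called genes overlapped more than chance in either direction (59 genes against 27.1, odds ratio 16.2, two-sided Fisher exact p = 4.15e-17), by a test that takes genes as independent. Both contrasts also share 1 estimate of spread per gene, which favours the same genes in both. The overlap alone therefore shows no shared effect. On the stage axis, E12 WT lay later than E12 DKO (0.096 to 0.516 against -0.007 to 0.005). The libraries labelled E18 WT lay earlier than E18 DKO (0.031 to 0.185 against 0.962 to 1.044). Whether the opposite directions follow from these positions rather than from genotype was not tested. Without E12 WT 1, 586 genes changed the same way (254 higher, 332 lower, against 334 and 503 for independent lists), 1091 went opposite ways, and Pearson's r was -0.129. The 4 genes became 1 without E12 DKO 1, 2 or 3. The 55 genes became 1, 0 and 1 without E12 DKO 1, 2 and 3, 228 and 5 without E12 WT 2 and 3, 13 and 13 without E18 DKO 1 and 3, and 9 and 11 without libraries 1 and 2 labelled E18 WT.

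The stage comparison within the wild-type groups asks how membranes mature, but rests on the labels in doubt above. The genes higher in the libraries labelled E18 WT included Noct, a circadian deadenylase-family gene (3.17 ± 0.44), Col2a1 (2.88 ± 0.57), the retinoic acid receptor Rarb (2.65 ± 0.52), the netrin receptor Unc5c (2.48 ± 0.48), Slfn9 (2.12 ± 0.30), the protocadherin-type Fat4 (1.94 ± 0.37), ccdc198 (3.81 ± 0.69) and the ribosomal gene Rps3a1 (2.08 ± 0.40). Most of the largest falls were in pseudogenes or near-identical copies, whose values are uncertain: Eno1b at -8.37 ± 0.64, Rps26-ps1 at -7.18 ± 0.74, Eif3j2 at -6.38 ± 0.67 and Hmga1b at -4.61 ± 0.94. Nudc-ps1 was 542-fold higher in E12 WT (95% counting interval 185 to 2630). Zfp990 was at -7.20 ± 1.09 and the mitochondrial transfer RNA mt-Ta at -4.67 ± 0.87 (-2.85 without E12 WT 3). Noct, Slfn9, Eno1b, Rps26-ps1 and Eif3j2 kept their calls with any 1 library left out, and each of the others lost its call in 3 or more of these 6 fits. In all 173 genes differed, 53 higher and 120 lower, with 3247 non-overlapping genes (17.9%, where chance gives 10%). The count was 1694 without E12 WT 1, 101 and 107 without E12 WT 2 and 3, and 38, 38 and 39 without libraries 1, 2 and 3 labelled E18 WT. It was 1223 by the DESeq2 Wald test, 52 when only these 6 libraries were fitted, and 272 (181 higher, 91 lower) by library size alone.

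Within the DKO groups the stages were far apart. Lcn2 was at 10.79 ± 1.32, from a mean of 0.826 CPM at E12 to 1469 CPM at E18. The early embryo gene Dppa3 was at least 185-fold and Csn2 at least 120-fold higher at E18, against a floor of 3 counts per library, while Csn1s2b was 2050-fold (95% counting interval 701 to 9940) and the ion channel gene Pkd2l1 1970-fold higher (353 to 77900). Among single genes lower at E18 were Bhmt, a methyltransferase of homocysteine, at -7.59 ± 0.75, the glycogen synthase Gys2 at -7.61 ± 1.00, A1cf at -6.78 ± 0.79, and Glyat, which was 813-fold higher at E12 (146 to 32100). Glp1r (-7.41 ± 0.90), Mmd2 (-7.32 ± 0.77), Gabrp (-7.53 ± 2.01) and Usp51 (-6.94 ± 0.83) were lower too, while Ces3a (10.54 ± 1.35), Vsig1 (9.92 ± 1.25) and the pseudogene Serpina4-ps1 (9.90 ± 1.62) were higher. Interferon-stimulated genes rose in 32 of 34 (33 adjusted over the list alone, adjusted p = 0.415 with an estimated correlation), and cell cycle genes fell in 34 of 35 (34 adjusted over the list alone, 0.435). In the same comparison all 18 immediate early genes, which can rise during tissue handling, rose (18 adjusted over the list alone, 0.415), with a median of 3.04, and 7 of 8 primitive erythroid genes fell (7 adjusted over the list alone, 0.625). In all 8349 genes differed, 4203 higher and 4146 lower, with 12192 non-overlapping genes (67.2%, where chance gives 10%). By library size alone the split was 2809 higher and 5947 lower, with the median of all genes shifted by -0.35.

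Because the DKO labels name a second strain, genes near the targeted loci were examined separately. Within 10 Mb of Dcn or Bgn, leaving both out, 1 of 176 tested genes was called at E12, Gm4925 on chromosome 10, a predicted gene without a named function that was noted after its value was seen (-4.53, adjusted p = 0.0366). Elsewhere 61 of 17975 were called (odds ratio 1.68, 95% interval 0.0416 to 9.83, two-sided Fisher exact p = 0.454). At E18, 83 of 176 were called near the loci against 7593 of 17975 elsewhere (odds ratio 1.22, 0.895 to 1.66, two-sided Fisher exact p = 0.193). Without E18 DKO 3 the odds ratio at E18 was 1.35 (two-sided Fisher exact p = 0.0497), and over all libraries left out in turn it ranged from 1.11 to 1.35. Genes of the X-inactivation centre and the Y chromosome, which mark the sex of the fetuses, did not pass between genotypes at E12 (0 of 4 in each list). The sexes were not balanced there, with high Xist in 2 of 3 E12 DKO and 1 of 3 E12 WT libraries, and with the Y-linked mean as a covariate the count of 64 became 1. The fold changes of the 64 moved little under it, all in the same direction, from a median absolute log2 value of 1.28 (median SE 0.20) to 1.22 (0.22), with Bgn at -4.65 and Dcn at -5.77. At E18, 1 of 4 X-inactivation genes, Ftx, was lower (-1.46 ± 0.37) and 0 of 4 Y-linked genes passed.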

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

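The test of the difference between stages was planned, while the tests of the 3 patterns after it were chosen only after their results were seen; the splits of the libraries and the tests near the targeted loci, reported under Other observations, were planned.

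The genotype effect differed between E18 and E12 in 7600 genes (41.9% of those tested) by the test of the difference itself. Among the 289 genes named in the genotype comparisons it differed in 230, but these were chosen from the same contrasts, which favours a high share. Only called genes with a conventional symbol and a mean of 5 CPM or more over all 12 libraries were ranked. Among them, the largest differences of log2 fold change in the positive direction were those of Rpl15-ps2 (19.5), Serpina4-ps1 (16.2), Ces3a (14.71), Vsig1 (14.38), Serpina3n (14.36) and Slc51b (14.07). In the negative direction they were those of Zfhx4 (-9.53), Glyat (-9.46), Col2a1 (-9.25), Prl7a2 (-8.67), Gabrp (-8.40) and Gria1 (-8.20). These sizes rest on fitted values with few counts in some groups, and 3 of the genes, Rpl15-ps2, Serpina4-ps1 and Prl7a2, belong to families that share reads. Rpl15-ps2 is also among the 17 genes switched between the wild-type groups, described below. Its CPM was 6.38, 0.0853 and 11.8 in the E18 DKO libraries, so its difference may not be a genotype effect that depends on stage.

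The 3 libraries labelled E18 WT resembled the E12 libraries: only 34 genes differed between them and E12 DKO (29 higher and 5 lower in E12 DKO, Bgn and Dcn among the lower), against 7678 between them and E18 DKO. A swap of the wild-type labels between the stages is argued against by the E12 WT libraries, the lowest of which lay at 0.096 on the axis between the DKO stages rather than near 1. A change in the share of red cells alone is argued against by the called markers of 15 other cell types. Of these, 62.2% moved the commoner way (69 higher and 42 lower, 95% interval 52.5 to 71.2%). A change in red cells alone would move nearly all alike, or leave them largely unmoved where TMM scaling removes the dilution. Called markers in both directions go with neither. The 15 include macrophage, neutrophil, lymphocyte and mast cell lists, so a change in the share of all blood cells was not tested. A stage other than the label and a genotype effect on maturation cannot be told apart by the axis. The highest position of these libraries, 0.185, only restates the resemblance, and no other E18 wild-type library was used. Both stay open, but not on equal terms. A genotype effect alone would need wild-type membranes at E18 to hold 74.8 to 87.8% embryonic beta-globin. E12 DKO held 82.3 to 85.1% and E18 DKO 1.33 to 2.67%. The E18 and difference counts therefore cannot be assigned to genotype alone.

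Between the 2 wild-type groups, which the labels give as the same strain, 17 genes were at 2 CPM or more in every E12 WT library and under 0.2 CPM in every library labelled E18 WT, and 0 the other way. They include Ifi202b, Col6a5, Eno1b, Rps2-ps10 and Nudc-ps1, named after their values were seen, and 13 of the 17 (76.5%, against 12.4% of tested genes) are predicted genes or pseudogenes. Stage is argued against for these 17, since 0% of them switched the same way between the DKO stages (95% interval up to 19.5%). A gene on in only some libraries of a DKO stage could not count as switched. Rps26-ps1, just outside the limits at up to 0.205 CPM in the libraries labelled E18 WT, did follow the stage labels in the DKO. It was at 8.91 to 12.3 CPM in E12 DKO and 0.11 to 0.436 CPM in E18 DKO. A difference of strain background between the wild-type groups may account for the 17 but stays open. Of the 17, 10 were on in some and off in other DKO libraries of 1 stage, as where 2 strain variants segregate. Among genes of like abundance 30 of 7371 were (odds ratio 343, interval 110 to 1160, Fisher exact p = 1.21e-19). The 17 were chosen for being off in a whole wild-type group, while the 7371 only had to be on in one. The contrast follows in part from that choice, so it cannot separate segregating variants from other on and off behaviour. Which strain each library carries stays open, because no sequence was available here and near-identical copies share reads.

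E12 WT 1 lay between the stages, at 0.516 on the axis and with 14.8% embryonic beta-globin. It held Xist at 80.6 CPM, 10.6% of the mean of the Xist-high libraries, and Y-linked transcripts at 90.4% of the mean of the Y-positive libraries, as may arise if RNA of animals of both sexes entered the library. Nothing in the tables excludes this, and library 3 of those labelled E18 WT, with Xist at 2.81% and Y-linked transcripts at 93%, shows the same to a lesser degree. A mixture of early and late membranes cannot be told apart from other causes, since the late fraction had a median of 0.39 over 677 rising and 0.78 over 494 falling genes, a difference of 0.39, with source profiles that had to be assumed. A real difference between litters of 1 stage was not tested and stays open.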

How the results depend on the processing

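The fit without 2 wild-type libraries was chosen after the data were seen; all other alternatives were planned. Genes changed at E18, the difference and the DKO stages kept their counts within 1.5 times under every alternative. The E12 count of 64 became 2073 with the DESeq2 Wald test, 0 with only the groups compared (fewer libraries and a spread from 6 of them), 1 with the Y-linked covariate, 1 with the replicate block, 3782 without the 2 wild-type libraries that stand apart (E12 WT 1 and library 3 labelled E18 WT), and 1 to 3248 leaving out each replicate. The wild-type stage count of 173 became 1223, 52, 34 with the block, 1040 and 38 to 1694, and 272 by library size alone. The 4 genes shared in direction became 46, 0, 1 with the block, 632 and 1 to 586; the 55 opposite became 1383, 0, 0 with the block, 1337 and 0 to 1091, and 36 with a 2-fold threshold. Called lists at E12 went from 10 to 0 with an estimated correlation, 0 with fry, 5 without the 2 libraries and 4 to 12 leaving out each replicate; at E18 from 10 to 0 with an estimated correlation and 18 with fry. Odds ratios near Dcn and Bgn ranged from 0 to 1.73 at E12 and 1.11 to 1.35 at E18 leaving out each replicate. Prelp at E12 turned from -0.42 to 1.27 without E12 WT 1 and to 1.27 without the 2 libraries, and was -0.87 without E12 WT 3. Apart from the changes that fewer libraries bring, the cause was not tested. By library size alone the splits became 41 higher and 14 lower at E12, 2382 and 6015 at E18, 2187 and 6438 for the difference, 181 and 91 for the wild-type stages, 2809 and 5947 for the DKO stages. Bgn and Dcn kept their direction throughout, but at E12 both missed the threshold with only the groups compared (adjusted p = 0.0714). Dcn also missed it with the block (0.101), the Y-linked covariate (0.0535) and without E12 DKO 1, 2 or 3 (0.0895, 0.0938, 0.109). Replicate numbers do not pair the libraries (correlations of same-numbered deviations from -0.176 to 0.18). The difference fitted to its own groups is the same fit and gave no value. Of simulated 2-fold changes, 9% were called at either stage.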

Other observations

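The splits of the libraries and the tests near the targeted loci were planned before their results were seen; the comparisons of the first paragraph were chosen only afterwards.

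Set side by side, E12 DKO and the libraries labelled E18 WT differed in few genes outside Bgn and Dcn. Zdhhc9 was lower in E12 DKO (-1.40 ± 0.22, n = 3 per group, adjusted p = 0.0299), as it was against E12 WT. Pop4, a ribonuclease P subunit, was lower (-1.62 ± 0.22), and Rab37 (3.95 ± 0.51), Wdfy1 (1.28 ± 0.19) and Trim34b (5.16 ± 0.71) were higher. Of the 29 higher genes most were predicted genes or pseudogenes, such as Rps26-ps1 (6.54 ± 0.73), whose values are uncertain. Without E12 WT 1 in the fit the count was 60. E18 DKO against E12 WT gave 5044 genes, and 8637 without E12 WT 1.

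With E12 WT 1 left out of the E12 comparison, embryonic globins were lower in the DKO, with Hbb-bh1 at -3.54 ± 0.52 and Hba-x at -3.13 ± 0.46, along with the troponin gene Tnni2 (-3.20 ± 0.74). The copper transporter Atp7a (3.61 ± 0.87), B3gnt3 (3.39 ± 0.48), the complement gene C6 (2.92 ± 0.68) and the protease Adamts12 (3.01 ± 0.78) were higher. Hba-a2 was higher by 4.24 ± 0.89 while its near-identical neighbour Hba-a1 was at -3.03 ± 0.46, so neither globin value can be read alone.

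The splits of 6 libraries into groups of 3 number 10 and are too few for a share under 0.05. The real splits gave 64 genes at E12, 7678 at E18, 173 for the wild-type stages and 8349 for the DKO stages, and the highest of the other splits gave 0, 0, 0 and 1, with 1 split as large, the real one, in each case. For the difference, 1 of 60 splits, the real one with 7600 genes, was as large. The highest of the others gave 5987, and the 5 large ones (1191 to 5987) all keep the real E18 groups. The rank among the 60 is therefore set by the E18 grouping rather than by the difference itself. The drawn splits that keep that grouping are too few for a share under 0.05, so chance is not excluded for the difference. Near the targeted loci the odds ratio of being called was 1.22 at E18, with an interval that includes 1 (0.895 to 1.66). Without E18 DKO 3 it was 1.35 (two-sided Fisher exact p = 0.0497). Local enrichment from a carried haplotype is therefore neither shown nor excluded at E18. Only 83 of the E18 calls beside the targeted genes lay in these windows, so the windows could not be a general source of the 7678 calls whatever the odds ratio. At E12 the odds ratio was 1.68, but with 1 called gene near the loci under 1 was to be foreseen by chance. The interval including 1 decides nothing there, and a carried haplotype cannot be told apart from no enrichment.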
